A study of Mus musculus with 12 samples.

How the data were processed

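Total RNA of livers from male mice was labelled with biotin and hybridised to 12 one-colour Affymetrix Mouse Genome arrays. The labels name genotype (wild type or Nrf2 null), treatment (vehicle or CDDO-Im), dose, given there as 30 uM/kg, route (gavage), time (6 hours) and a replicate number. These made 4 groups of 3 arrays, taken from the labels alone. The labels do not say whether each array came from a separate animal, so the p-values measure the spread between these samples. The titles of all 6 vehicle arrays carry a mark, the digit 2 in brackets, that no CDDO-Im title carries. Its meaning is not stated, and whatever it marks cannot be told apart from the compound.

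The values were deposited as log2 intensities, 1 per probe set and array, made by RMA per the submitters' processing notes, without a version. The file held 45101 probe sets, 64 of them controls, with no missing or negative value and array medians within 0.1 of each other. Values were used as deposited. The number of arrays limits the precision, and signal over background was not used here. Of the other probe sets 34945 named 1 gene, 932 several and 9160 none. Symbols were updated by Entrez Gene id, which matched 34741 probe sets and changed 0 symbols. A gene was represented by the single-gene probe set with the highest mean over all arrays, which left 18193 genes to test. No gene was left out for low signal. Probe sets naming several genes or none were left out of the comparisons and tested apart. The mouse gene annotation GRCm38.p6 served for names and for which genes share a chromosome.

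A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, and its moderated test (two-sided) was applied to 5 comparisons. These were CDDO-Im against vehicle in each genotype, Nrf2 null against wild type under each treatment, and the interaction, the wild type effect of CDDO-Im minus the Nrf2 null effect. The prior had 3.8078 degrees of freedom and the residual 8. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. Differences are in log2, errors of differences are the model's standard errors, and errors of group means are SD over 3 arrays. Shared calls were set against the number expected if both calls were independent. Whether groups overlapped was counted for each gene, where 10% of genes separate by chance with 3 against 3 arrays and the smallest exact permutation p is 0.1.

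The comparisons, the model, the lists of genes, the rule for naming genes and most alternatives were fixed before the data were examined. There were 27 gene lists and 10 lists of cell type markers, with 610 of 679 members measured. They covered Nrf2 pathway regulators, glutathione synthesis and recycling, glutathione S-transferases, quinone, carbonyl, epoxide and ester detoxification, thioredoxin, peroxiredoxin, heme and iron, NADPH supply, glucuronidation, efflux transporters, proteasome subunits, cytochrome P450 genes, cholesterol and fatty acid synthesis, fatty acid oxidation, bile acids, gluconeogenesis, the acute phase, cytokines and NF-kB targets, interferon response, ATF4, endoplasmic reticulum chaperones, heat shock, p53, the clock, cell cycle, ribosome biogenesis, and male-biased and female-biased liver genes. The marker lists covered hepatocytes, Kupffer cells, neutrophils, lymphocytes, endothelial cells, stellate cells, cholangiocytes, erythroid cells, pancreatic acinar cells and adipocytes. Each list was tested with camera at a preset correlation of 0.01 in each comparison, with Benjamini-Hochberg adjustment over all 185 tests. By camera 81 tests passed. With an estimated correlation 9 passed: the quinone and thioredoxin lists in wild type, the regulator, glutathione synthesis, quinone, thioredoxin and NADPH lists between genotypes under CDDO-Im, and the glutathione synthesis and thioredoxin lists for the interaction. Once Nfe2l2, whose level the genotype fixes, was left out of the regulator list, 6 did, without the regulator and NADPH lists between genotypes and glutathione synthesis for the interaction. By fry, which tests whether the members move on balance 1 way, 36 passed.

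Genes could be named if they were among the 8 largest rises or 8 largest falls called in a comparison with no overlap between the groups' arrays (for the interaction, called), leaving out clone and model names, or among the 4 members of a list with the smallest adjusted p. Nfe2l2, Keap1, Nqo1, Gclc, Gclm, Hmox1, Txnrd1 and Srxn1 could be named always. A gene named for 1 comparison could be given in the others.

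The methods were tested on simulated data, in which the fit called 98% of 100 genes changed by 1 log2 unit and 100% of 100 changed by 2 log2 units in wild type, and 93% and 100% for the interaction. False calls were 9 of 207 in wild type, 8 of 206 between genotypes under CDDO-Im and 6 of 199 for the interaction. Simulated genes vary independently, which real genes do not. The simulation also used normal noise without an outlying array, and 200 changed genes. The shares recovered therefore do not carry over to the real arrays, where a gene not called may still have changed.

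The alternatives were the replicate number as a block, array medians aligned, the 75th percentile aligned, cyclic loess, a filter that left out the dimmest 40% of probe sets, the mean of all probe sets of a gene, every probe set as the tested unit, a variance model with trend and robust estimation, array weights, only the arrays compared, a 1.5-fold minimum, an adjusted p under 0.01, and each array left out in turn. Leaving out together the 2 arrays with pancreatic acinar transcripts was added after the data had been seen. The replicate numbers were taken not to pair the samples, since 18 pairs of arrays with the same number had correlations of residuals from -0.30 to 0.28, with a median of 0.014 against 0.012 for different numbers. Other splits of the 6 arrays were counted for each comparison of groups, and 100 of 200 splits for the interaction. Fisher's exact test was used for counts of genes by chromosome.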

Results

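RNA from livers of male mice was hybridised to 12 single-colour expression arrays, whose number limits the precision. The mice were wild type or lacked Nrf2, the transcription factor encoded by Nfe2l2 that switches on antioxidant and detoxification genes. Each genotype received vehicle or CDDO-Im, a synthetic triterpenoid known to activate Nrf2, by gavage, and 6 hours later livers were taken, which gave 4 groups of 3 arrays. The median log2 value lay between 5.77 and 5.84 on the 12 arrays. The mean correlation of an array with the others of its group, across probe sets, lay between 0.983 and 0.994. It was lowest in wild type vehicle replicate 3, whose mean correlation with the CDDO-Im arrays was 0.989. On the first principal component this array scored 10.12, the other vehicle arrays -29.88 to -16.23 and the CDDO-Im arrays 3 to 25.41.

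Nfe2l2 (Entrez Gene 18024) was read first in every array. Its brighter probe set read 8.60 ± 0.09 in wild type with vehicle and 8.73 ± 0.39 in wild type with CDDO-Im (log2, mean ± SD, n = 3 each). In the Nrf2 null livers it read 4.71 ± 0.24 with vehicle and 4.89 ± 0.10 with CDDO-Im, and all 6 null arrays lay below all 6 wild type arrays. The difference between genotypes was -3.89 with vehicle (adjusted p = 7.01e-07) and -3.84 with CDDO-Im (adjusted p = 2.73e-07). A dimmer probe set of the gene read 4.90 ± 0.15, 4.68 ± 0.05, 5.04 ± 0.21 and 4.92 ± 0.15 in the same order of groups, with null minus wild type at 0.14 and 0.24. The transcript of Keap1, the protein that holds Nrf2 in check, did not pass the test in any comparison.

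**Figure D1:**
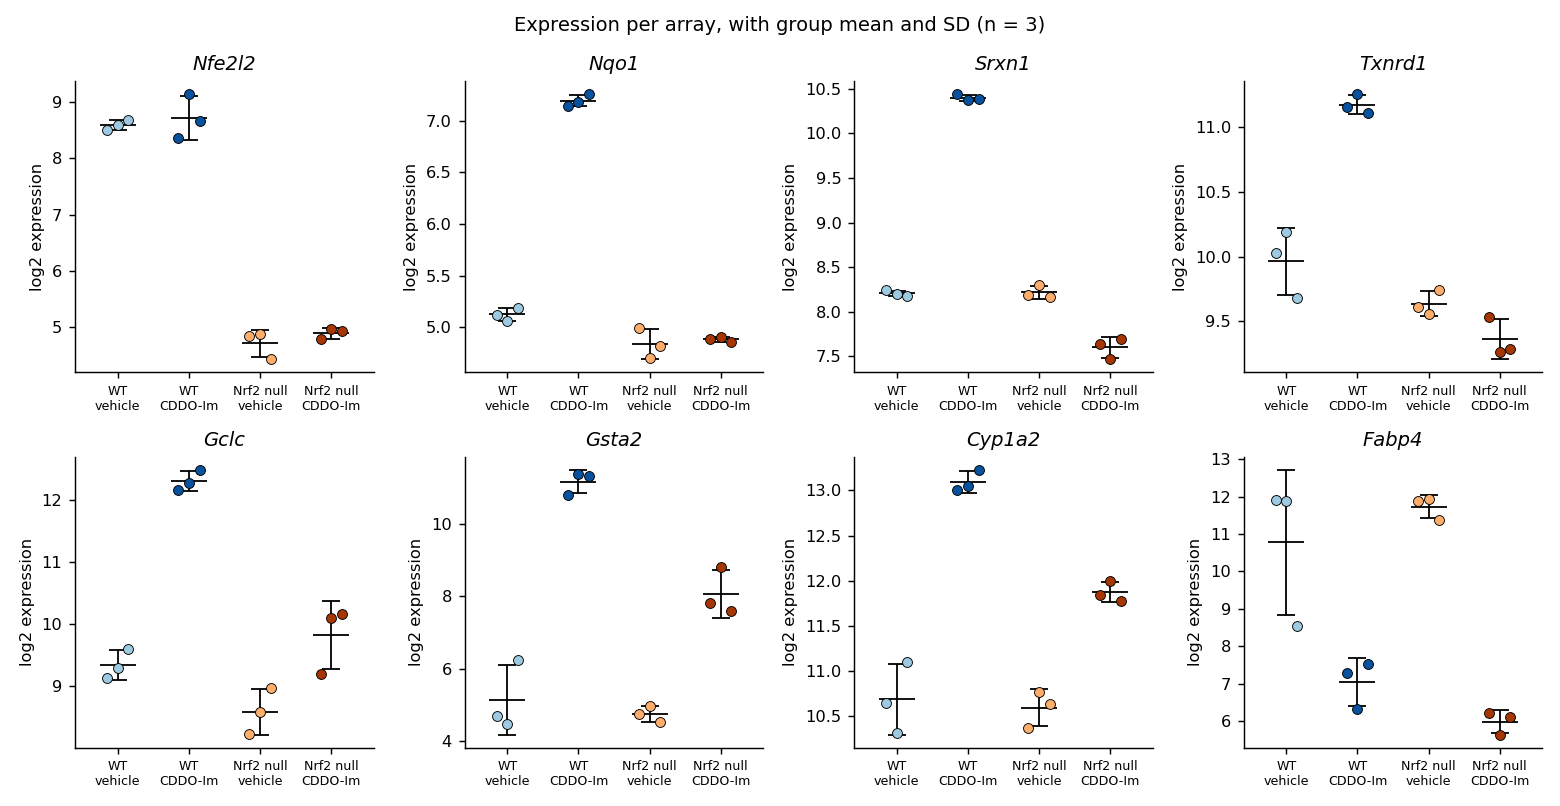
Expression (log2) of 8 genes on each of the 12 arrays, 1 point per array, with a bar at the group mean and whiskers of 1 SD (n = 3). Nqo1, Srxn1 and Txnrd1 rose with CDDO-Im in wild type and did not rise in Nrf2 null livers, Gclc, Gsta2 and Cyp1a2 rose in both genotypes, and Fabp4 fell in both.

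The effect of CDDO-Im where Nrf2 was present was asked of the wild type livers. Genes of quinone, glutathione and thioredoxin metabolism rose. Nqo1 (Entrez Gene 18104), which reduces quinones, rose from 5.12 ± 0.06 to 7.20 ± 0.06 (log2, mean ± SD, n = 3), a difference of 2.07 ± 0.08 (SE, adjusted p = 7.28e-08). Srxn1 (Entrez Gene 76650), which repairs oxidised peroxiredoxins, rose 4.57-fold (2.19 ± 0.07, adjusted p = 2.75e-08). Gclc (Entrez Gene 14629), the catalytic subunit of the enzyme that starts glutathione synthesis, rose 7.81-fold (2.97 ± 0.25, adjusted p = 6.52e-05). Gsta2 (Entrez Gene 14858), a glutathione S-transferase, rose by 6.02 ± 0.41 (adjusted p = 1.11e-05). Nqo1, Ces1g, Cbr3 and Lyve1 on all 3 wild type vehicle arrays and Gsta2 on 2 of them (4.71 and 4.49, with 6.25 in replicate 3) read below the array medians, and signal over background was not used here, so the sizes of their rises are uncertain and not given as folds. Ces1g, Aox1, Abcc3 and Gstm4 rose by 3.61, 3.18, 2.98 and 2.97. Hmox1, which degrades heme, differed by 0.58 ± 0.15 and did not pass the test (adjusted p = 0.0856). Among the genes that went down, Fabp5, a fatty acid binding protein, fell by 2.96 (adjusted p = 0.0021) and Lcn2, a siderophore-binding acute phase protein, fell by 5.38 (adjusted p = 0.0429). The largest rises and falls were named among genes whose 3 CDDO-Im arrays all lay on 1 side of the 3 vehicle arrays.

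The detoxification lists moved up as sets in wild type. Of 20 glutathione S-transferases 11 rose, and 12 did when adjusted over the list alone (camera adjusted p = 1.28e-18, and adjusted p = 0.129 with an estimated correlation). Of 20 quinone, carbonyl, epoxide and ester detoxification genes 8 rose, or 14 adjusted over the list alone, among them Cbr1 by 2.73 and Cbr3 by 2.01 (camera adjusted p = 1.28e-18, and adjusted p = 0.0383 with an estimated correlation). In the list of thioredoxin, peroxiredoxin, heme and iron genes 7 of 16 rose, or 10 with 2 lowered adjusted over the list alone, including Txnrd1 by 1.21 and Blvrb by 2.24 (camera adjusted p = 6.31e-12, and adjusted p = 0.00913 with an estimated correlation). Glutathione synthesis and recycling had 3 of 10 members raised, Gclc, Gclm (0.94) and Gsr (1.96), and 4 raised with 1 lowered adjusted over the list alone (camera adjusted p = 0.00109, and adjusted p = 0.123 with an estimated correlation). The list of NADPH suppliers had 3 of 7 raised, Pgd (2.12), Tkt (1.67) and Me1 (1.51), or 4 adjusted over the list alone (camera adjusted p = 1.91e-06, and adjusted p = 0.0965 with an estimated correlation). Glucuronidation genes rose in 8 of 12 cases, or 10 adjusted over the list alone, with Ugdh, which makes UDP-glucuronate, up by 2.83 (camera adjusted p = 3.18e-17, and adjusted p = 0.123 with an estimated correlation). Efflux transporters rose in 6 of 15 cases, or 9 adjusted over the list alone (camera adjusted p = 5.2e-09, and adjusted p = 0.177 with an estimated correlation). Of 31 cytochrome P450 genes and their regulators 4 rose, with Cyp1a2 up by 2.40, and Cyp3a13 fell by 1.43. Adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 2.46e-06, and adjusted p = 0.237 with an estimated correlation). In wild type vehicle replicate 3 the medians of the glutathione S-transferase, glucuronidation, efflux transporter, quinone detoxification and cytochrome P450 lists lay 0.83, 0.84, 0.44, 0.42 and 0.27 above the other vehicle arrays of that genotype, and those of the thioredoxin, NADPH and glutathione synthesis lists 0.00, 0.02 and 0.07.

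Secreted inflammation proteins and folding factors of the secretory pathway moved down in wild type. Of 23 acute phase genes 9 fell, or 22 adjusted over the list alone, with Fgg, a fibrinogen chain, at -0.54 and Lbp at -1.27 (camera adjusted p = 9.86e-21, and adjusted p = 0.204 with an estimated correlation). Of 19 endoplasmic reticulum chaperone genes 12 fell, or 16 with 1 raised adjusted over the list alone, among them Hyou1 at -1.33 and Sdf2l1 at -2.23 (camera adjusted p = 9.57e-17, and adjusted p = 0.23 with an estimated correlation). Wild type vehicle replicate 3 stood apart in these lists. Its chaperone median was -0.22 against 0.99 and 1.06 in replicates 1 and 2, and its acute phase median -0.03 against 0.61 and 0.54 (log2 deviation from the mean of the 12 arrays). The same array carried transcripts of pancreatic acinar cells, which make digestive enzymes, at a list median of 3.74. Nrf2 null vehicle replicate 2 carried them at 2.06, and the other 10 arrays lay between -0.71 and -0.44. The acinar list differed by a median of -1.33 between the wild type groups (camera adjusted p = 0.00885, and adjusted p = 0.704 with an estimated correlation), no member passed singly, and without wild type vehicle replicate 3 its mean difference was 0.09 (adjusted p = 0.814).

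Other lists rose in wild type with few members called singly. Heat shock genes rose in 4 of 18 cases, or 10 adjusted over the list alone, with Stip1 up by 0.78 and Chordc1 by 0.98 (camera adjusted p = 1.53e-08, and adjusted p = 0.237 with an estimated correlation). In wild type vehicle replicate 3 their median lay 0.41 above the other vehicle arrays, beside a median effect of 0.51. Ribosome biogenesis genes rose in 3 of 25 cases, or 8 adjusted over the list alone, with Myc up by 1.14 (camera adjusted p = 2.76e-09, and adjusted p = 0.129 with an estimated correlation). Fatty acid oxidation genes rose in 2 of 25 cases, or 4 adjusted over the list alone, namely Fgf21, a fasting hormone of the liver, by 1.89 and Pex11a by 1.19 (camera adjusted p = 0.00112, and adjusted p = 0.63 with an estimated correlation). Lyve1, a receptor of sinusoidal endothelium, rose by 2.26 (adjusted p = 0.0013). In Nrf2 null livers it did not pass, and the difference between genotypes was 2.03 (adjusted p = 0.133). Lyve1 read below the array medians in all groups but wild type with CDDO-Im, so these sizes are uncertain. The endothelial marker list as a whole had a median of -0.165 in wild type and did not pass with all arrays.

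In wild type 332 of 18193 genes passed limma's test at an adjusted p under 0.05, 178 higher and 154 lower, 129 of them at least 2-fold, and 2483 had an unadjusted p under 0.05. Groups did not overlap for 16.6% of all genes, where chance gives 10%. Leaving out wild type vehicle replicates 1, 2 or 3 changed the count to 104, 117 or 1385, and leaving out wild type CDDO-Im replicates 1, 2 or 3 changed it to 212, 134 or 156. It was 1293 without both arrays that carried acinar transcripts, 2023 with array weights, 549 with every probe set, 110 with the compared arrays alone and 109 at an adjusted p under 0.01. The calls of Nqo1, Srxn1, Gclc, Gclm, Gsr, Txnrd1, Gsta2, Ces1g, Aox1, Abcc3, Gstm4, Cbr1, Cbr3, Blvrb, Pgd, Tkt, Me1, Ugdh, Cyp1a2, Cyp3a13, Fgf21, Pex11a, Lyve1, Fabp5, Fgg and Hyou1 held whichever array was left out, and of these Pex11a, Fgg and Hyou1 lost theirs with the compared arrays alone, and Fgg with a 1.5-fold minimum. Without wild type vehicle replicate 1 the adjusted p was 0.19 for Lcn2, 0.0527 for Lbp, 0.0939 for Sdf2l1, 0.0599 for Stip1, 0.0751 for Chordc1, 0.113 for Fabp4 and 0.136 for Myc, the highest over the arrays left out. In all, leaving out 1 array ended the call of Lcn2 in 9 cases, Myc and Fabp4 in 5, Sdf2l1 in 4, Stip1 and Chordc1 in 2 and Lbp in 1.

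The effect of CDDO-Im where Nrf2 was absent was asked of the Nrf2 null livers. Gsta3 (Entrez Gene 14859) and Gsta2, both glutathione S-transferases, rose 11.4-fold (3.51 ± 0.60, SE, adjusted p = 0.011) and by 3.31 ± 0.41 (adjusted p = 0.00407, n = 3 per group), the latter from vehicle values of 4.54 to 4.96, below the array medians. Inmt, a methyltransferase, rose by 3.97 and Car3, a carbonic anhydrase, by 4.75 (adjusted p = 0.0365). Fabp4 (Entrez Gene 11770), a fatty acid binding protein of adipocytes and macrophages, fell by 5.74 ± 0.70 (adjusted p = 0.00407), and in wild type it fell by 3.73 (adjusted p = 0.0217). Nnmt, which methylates nicotinamide, fell by 5.39 (adjusted p = 0.0126), to 8.38, 5.74 and 5.52 in CDDO-Im replicates 1, 2 and 3. Below the array medians lay 2 of these values and 1 of the CDDO-Im values of Fabp4 (5.64), so both sizes are uncertain. Cxcl1, a chemokine that draws neutrophils, fell by 2.31 (adjusted p = 0.000232). Of the Nrf2 target genes named in advance, Gclc rose by 1.23 (adjusted p = 0.0171) and Srxn1 fell by 0.62 (adjusted p = 0.00405). Nqo1 (0.04), Gclm (0.23), Hmox1 (0.10) and Txnrd1 (-0.27) did not pass.

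**Figure D2:**
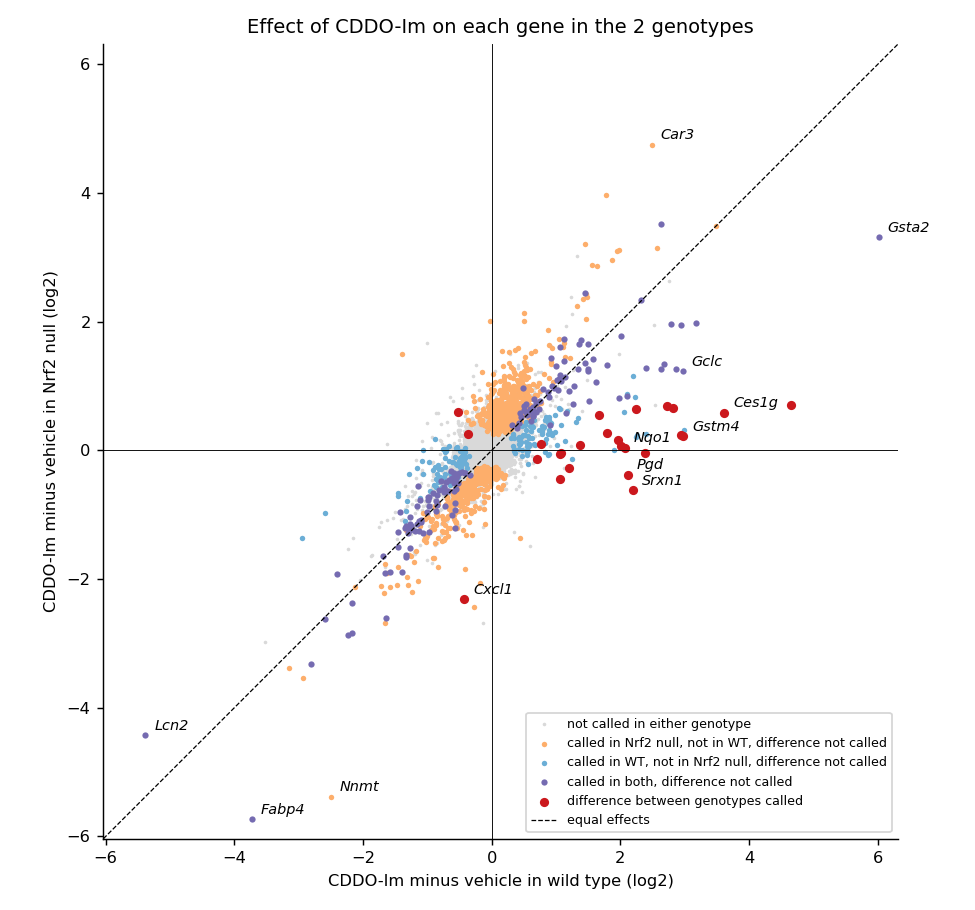
Effect of CDDO-Im (log2, CDDO-Im minus vehicle) on each of 18193 genes in wild type (horizontal) and in Nrf2 null livers (vertical), 1 point per gene, coloured by where the gene passed the test. The 25 genes in red are those whose effect differed between the genotypes, and 22 of them rose in wild type and lie below the dashed line of equal effects.

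Several lists of metabolic genes moved up in the Nrf2 null livers. Of 20 glutathione S-transferases 8 rose, or 12 adjusted over the list alone (camera adjusted p = 6.76e-09, and adjusted p = 0.242 with an estimated correlation). Of 20 quinone, carbonyl, epoxide and ester detoxification genes 8 rose, or 10 adjusted over the list alone, with Aox1 up by 1.98 and Aldh3a2 by 2.04 (camera adjusted p = 2.75e-05, and adjusted p = 0.234 with an estimated correlation). Glucuronidation genes rose in 6 of 12 cases, or 9 adjusted over the list alone, with Ugt2b1 up by 1.78 (camera adjusted p = 3.99e-08, and adjusted p = 0.237 with an estimated correlation). Of 31 cytochrome P450 genes and their regulators 10 rose and 1 fell, or 15 and 1 adjusted over the list alone, with Cyp2c29 up by 2.45 and Cyp1a2 by 1.28 (camera adjusted p = 1.22e-06, and adjusted p = 0.234 with an estimated correlation). Fatty acid oxidation genes rose in 8 of 25 cases, or 10 adjusted over the list alone, with Ppara, the receptor that drives them, up by 1.22 (camera adjusted p = 1.81e-06, and adjusted p = 0.446 with an estimated correlation). Fatty acid synthesis genes rose in 5 of 21 cases and 1 fell, or 11 and 1 adjusted over the list alone, with Dgat2 up by 0.90 and Elovl5 by 1.07 (camera adjusted p = 1.91e-06, and adjusted p = 0.237 with an estimated correlation). Bile acid synthesis and uptake genes rose in 7 of 18 cases and 1 fell, with the same counts adjusted over the list alone, and Cyp27a1, an enzyme of bile acid synthesis, was up by 1.11 (camera adjusted p = 0.000399, and adjusted p = 0.206 with an estimated correlation).

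Clock genes rose in 2 of 18 cases in the Nrf2 null livers, or 9 adjusted over the list alone, with Hlf up by 0.53 (camera adjusted p = 4.02e-05, and adjusted p = 0.206 with an estimated correlation), and did not pass as a set in wild type (camera adjusted p = 0.594). Efflux transporters rose in 3 of 15 cases, or 7 adjusted over the list alone (camera adjusted p = 0.000801, and adjusted p = 0.422 with an estimated correlation). Heat shock genes rose in 3 of 18 cases, or 5 adjusted over the list alone (camera adjusted p = 0.0037, and adjusted p = 0.583 with an estimated correlation). Interferon response genes rose in 2 of 21 cases, or 6 adjusted over the list alone (camera adjusted p = 0.000365, and adjusted p = 0.343 with an estimated correlation).

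Acute phase and chaperone genes moved down in the Nrf2 null livers. Of 23 acute phase genes 13 fell, or 19 adjusted over the list alone, with Saa3 at -2.84 and Serpina3n at -1.52 (camera adjusted p = 1.14e-13, and adjusted p = 0.242 with an estimated correlation). Nrf2 null CDDO-Im replicate 1 stood apart in this list, with a median of 0.07 against -0.61 and -0.37 in replicates 2 and 3 (log2 deviation from the mean of the 12 arrays), and Lcn2 read 12.33 there against 6.39 and 9.02. Of 19 endoplasmic reticulum chaperone genes 15 fell, or 17 adjusted over the list alone, with Manf at -2.61, Hyou1 at -1.65 and Xbp1, a transcription factor of the unfolded protein response, at -1.01 (camera adjusted p = 5e-17, and adjusted p = 0.23 with an estimated correlation). The thioredoxin, peroxiredoxin, heme and iron list did not pass as a set (camera adjusted p = 0.344), with 4 of 16 genes raised and 1 lowered, or 5 and 3 adjusted over the list alone. Neither did the NADPH suppliers (camera adjusted p = 0.618), with 2 of 7 raised and 1 lowered and a median of -0.07 beside a mean of 0.11, nor glutathione synthesis (camera adjusted p = 0.993), with Gclc alone called among 10 genes. Of 22 cytokines and NF-kB targets 4 fell and 1 rose, and Socs3, an inhibitor of cytokine signalling, fell by 3.55. That list did not pass (camera adjusted p = 0.702), with a median of 0.02 and a mean of -0.22. Among neutrophil markers 2 of 9 fell, S100a8 at -1.27 and S100a9 at -0.95, the former from values that lay below the array medians on all 3 CDDO-Im arrays and 1 vehicle array. The acinar list differed by a median of -0.87 (camera adjusted p = 0.207) and passed in 4 of 24 alternatives (down to 0.0116, with array weights).

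**Figure D3:**
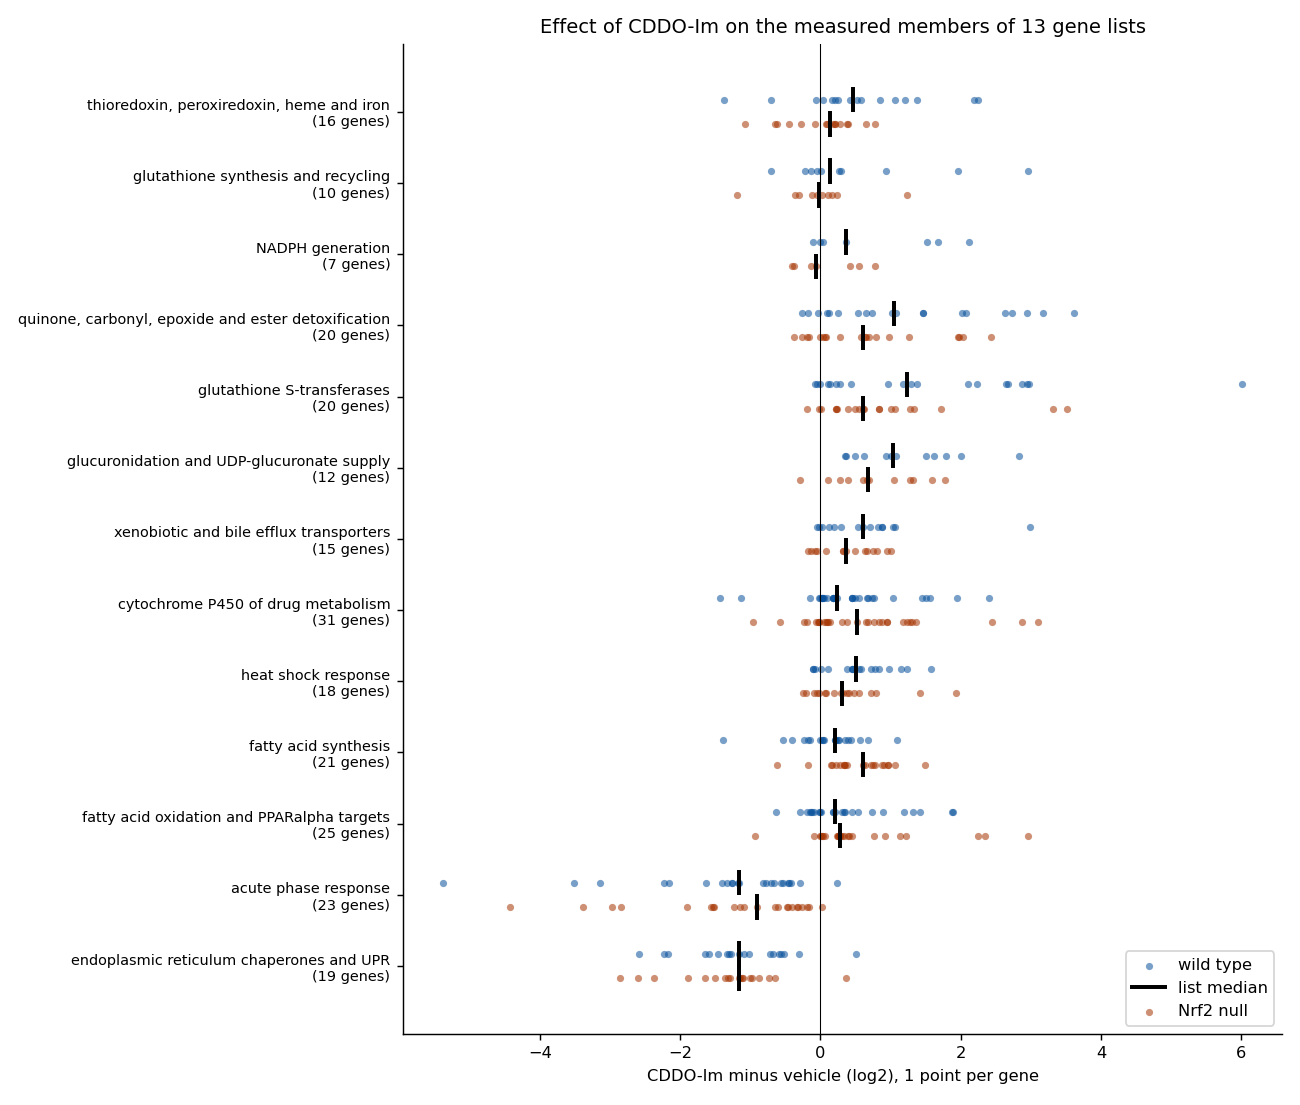
Effect of CDDO-Im (log2, CDDO-Im minus vehicle) on every measured member of 13 gene lists in wild type (blue) and Nrf2 null livers (brown), 1 point per gene, with a black bar at each list's median. With all arrays chaperone genes had a median of -1.16 in both genotypes. Wild type vehicle replicate 3 differed from the other wild type vehicle arrays by a chaperone median of -1.08, which lessened the wild type fall, so equal effects are not shown. The thioredoxin, peroxiredoxin, heme and iron list had 0.47 in wild type and 0.13 in Nrf2 null.

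In the Nrf2 null livers 1074 of 18193 genes passed limma's test at an adjusted p under 0.05, 652 higher and 422 lower, 234 of them at least 2-fold, and 3528 had an unadjusted p under 0.05. Groups did not overlap for 23.1% of all genes, where chance gives 10%. Leaving out Nrf2 null vehicle replicates 1 or 2 changed the count to 249 or 348, Nrf2 null CDDO-Im replicates 2 or 3 to 278 or 97, and wild type vehicle replicate 3 to 1615. It was 1155 without both arrays that carried acinar transcripts, 1897 with array weights, 97 at an adjusted p under 0.01 and 624 with at least a 1.5-fold change. With all arrays the count exceeded the 332 of wild type, but this order turned around in 5 alternatives. Wild type then had 1293 without both arrays that carried acinar transcripts, 2023 with array weights, 109 at an adjusted p under 0.01, 279 without Nrf2 null vehicle replicate 1 and 276 without Nrf2 null CDDO-Im replicate 3. The calls of Gsta2, Cyp2c29, Cyp1a2, Fabp4, Cxcl1, Srxn1, Aox1, Ugt2b1, Dgat2, Elovl5, Cyp27a1, Manf, Hyou1 and Xbp1 held whichever array was left out. Without Nrf2 null CDDO-Im replicate 3 the adjusted p was 0.0526 for Gsta3, 0.0551 for Aldh3a2, 0.0567 for Serpina3n, 0.062 for Nnmt, 0.0671 for Inmt, 0.079 for Gclc, 0.0798 for Hlf, 0.118 for S100a9, 0.131 for Socs3, 0.146 for Lcn2 and 0.132 for Car3, and it was 0.0546 for each of Ppara, Saa3 and S100a8. These were the highest values over the arrays left out, and leaving out 1 array ended the call in 9 cases for Lcn2, 8 for Car3, 5 for Socs3, 4 for Inmt, Gclc, Hlf and S100a9, 3 for Nnmt, 2 for Serpina3n and 1 for the others.

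Whether the effect of CDDO-Im depended on Nrf2 was tested as the effect in wild type minus the effect in Nrf2 null livers. Antioxidant and NADPH-supplying enzymes were among the genes that differed. Srxn1 differed by 2.81 ± 0.10 (SE, adjusted p = 8.7e-08), with 2.19 in wild type and -0.62 in Nrf2 null. Nqo1 differed by 2.03 ± 0.11 (adjusted p = 5.04e-06), and Pgd (Entrez Gene 110208), of the pentose phosphate pathway, by 2.50 ± 0.19 (adjusted p = 6.58e-05). Gsr, which recycles glutathione, differed by 1.80 (adjusted p = 0.000122) and Txnrd1, which reduces thioredoxin, by 1.48 (adjusted p = 0.00332). Ces1g (3.03), Gstm4 (2.75), Gstm3 (2.71), Pir (2.43), Cbr1 (2.03), Cbr3 (1.95), Blvrb (1.60) and Ugt2b35 (1.52) also differed. Nqo1, Ces1g and Cbr3 read below the array medians in all groups but wild type with CDDO-Im, so their sizes are uncertain. For Gclc the difference was 1.73 ± 0.35 and did not pass (adjusted p = 0.155), nor did those of Gclm (0.71, adjusted p = 0.133) and Gsta2 (2.71, adjusted p = 0.179). Cxcl1 differed by 1.88 (adjusted p = 0.00715), with a fall in Nrf2 null and no call in wild type. Sc5d, of cholesterol synthesis, differed by -1.12 (adjusted p = 0.0284).

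Among the lists, thioredoxin, peroxiredoxin, heme and iron genes differed upwards in 5 of 16 cases, or 6 adjusted over the list alone (camera adjusted p = 1.61e-07, and adjusted p = 0.0331 with an estimated correlation). Glutathione synthesis genes did so in 1 of 10 cases, or 4 adjusted over the list alone (camera adjusted p = 1.22e-05, and adjusted p = 0.0464 with an estimated correlation, or 0.0522 when Nfe2l2 was left out of the list of regulators tested beside it). NADPH suppliers differed in 2 of 7 cases, or 3 adjusted over the list alone (camera adjusted p = 1.22e-06, and adjusted p = 0.0951 with an estimated correlation). Quinone, carbonyl, epoxide and ester detoxification genes differed upwards in 4 of 20 cases, or 7 with 1 downwards adjusted over the list alone (camera adjusted p = 5.6e-08, and adjusted p = 0.161 with an estimated correlation). Glutathione S-transferases differed in 2 of 20 cases, or 7 adjusted over the list alone (camera adjusted p = 7.26e-05, and adjusted p = 0.485 with an estimated correlation). The acute phase list had a median difference of -0.13 (camera adjusted p = 0.207) and the chaperone list 0.15 (camera adjusted p = 0.0696), with no member of either called. Some lists that did not pass here with all arrays did so in alternatives. The chaperone list passed in 9 of 24, with an adjusted p down to 0.000132 and a mean of 0.39 without wild type vehicle replicate 2, and the acute phase list in 5, with 5.49e-05 and -0.40 without wild type vehicle replicate 3. The direction of the chaperone list was not stable. Without wild type vehicle replicate 3 its mean genotype difference with vehicle was -0.46, and its interaction mean was negative. Hepatocyte markers passed in 6, bile acid genes and cholangiocyte markers in 5 each, endothelial and acinar markers in 4 each, p53 targets in 3, ATF4 and proteasome genes in 2 each, and Kupffer cell, cytochrome P450 and cell cycle lists in 1 each. Fatty acid synthesis genes had a mean difference of -0.44 (camera adjusted p = 5.09e-05, and adjusted p = 0.34 with an estimated correlation), with no member called over all genes and 3 lower adjusted over the list alone.

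The difference between genotypes passed limma's test for 25 genes, 23 with a higher and 2 with a lower effect in wild type, and 1291 genes had an unadjusted p under 0.05. All of these but Cxcl1 and Sc5d, 23 genes, were among the 332 called in wild type and had the same direction there, where 0.25 would be shared by chance if both tests were independent. Both use the wild type arrays, so the tests are not independent. Leaving out wild type vehicle replicate 3 changed the 25 and the 23 to 46 and 44, wild type CDDO-Im replicate 2 to 15 and 14, Nrf2 null vehicle replicate 2 to 16 and 14, and Nrf2 null CDDO-Im replicates 2 or 3 to 15 and 14 or 16 and 15. They were 57 and 52 with every probe set, 89 and 72 with array weights, 39 and 36 without both arrays that carried acinar transcripts, and 15 and 14 at an adjusted p under 0.01. The calls of Srxn1, Nqo1, Pgd, Gsr, Txnrd1, Ces1g, Gstm4, Gstm3, Pir, Cbr1, Cbr3, Blvrb, Ugt2b35 and Cxcl1 held whichever array was left out, and that of Cxcl1 ended with the mean of its probe sets. Sc5d lost its call in 10 of 12 such fits, with an adjusted p of up to 0.123, reached without Nrf2 null vehicle replicate 2.

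Much of the response was common to both genotypes. Across all genes the effects of CDDO-Im in wild type and in Nrf2 null livers correlated at r = 0.667, a value across genes, which are not independent replicates. Of the 332 genes called in wild type 302 had the same sign in Nrf2 null livers. The median effect of the genes that rose in wild type was 0.89 there and 0.43 in Nrf2 null, and of those that fell -0.78 and -0.49. Both genotypes shared 148 calls in the same direction, 72 higher and 76 lower, where 6.38 and 3.57 would be shared if the calls were independent. The compared groups share no array, but both comparisons take their spread from all 12 arrays, so the calls are not independent. The mark on the vehicle titles separates the treatments alike in both genotypes. Whatever it stands for cannot be told apart from a common response to the compound. Opposite calls were made for 2 genes, Srxn1 and Lgr4, the latter with -0.36 in wild type and 0.26 in Nrf2 null. Gsta2, Aox1 and Cyp1a2 were among the shared rises and Fabp4, Lcn2, Hyou1 and Sdf2l1 among the shared falls. The 148 became 35, 45 or 772 without wild type vehicle replicates 1, 2 or 3, and 85, 45 or 54 without wild type CDDO-Im replicates 1, 2 or 3. Without Nrf2 null vehicle replicates 1, 2 or 3 it was 48, 56 or 97, and without Nrf2 null CDDO-Im replicates 2 or 3 it was 41 or 28. It was 637 without both arrays that carried acinar transcripts, 758 with array weights, 86 with array medians aligned, 40 with the compared arrays alone and 11 at an adjusted p under 0.01.

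**Figure D4:**
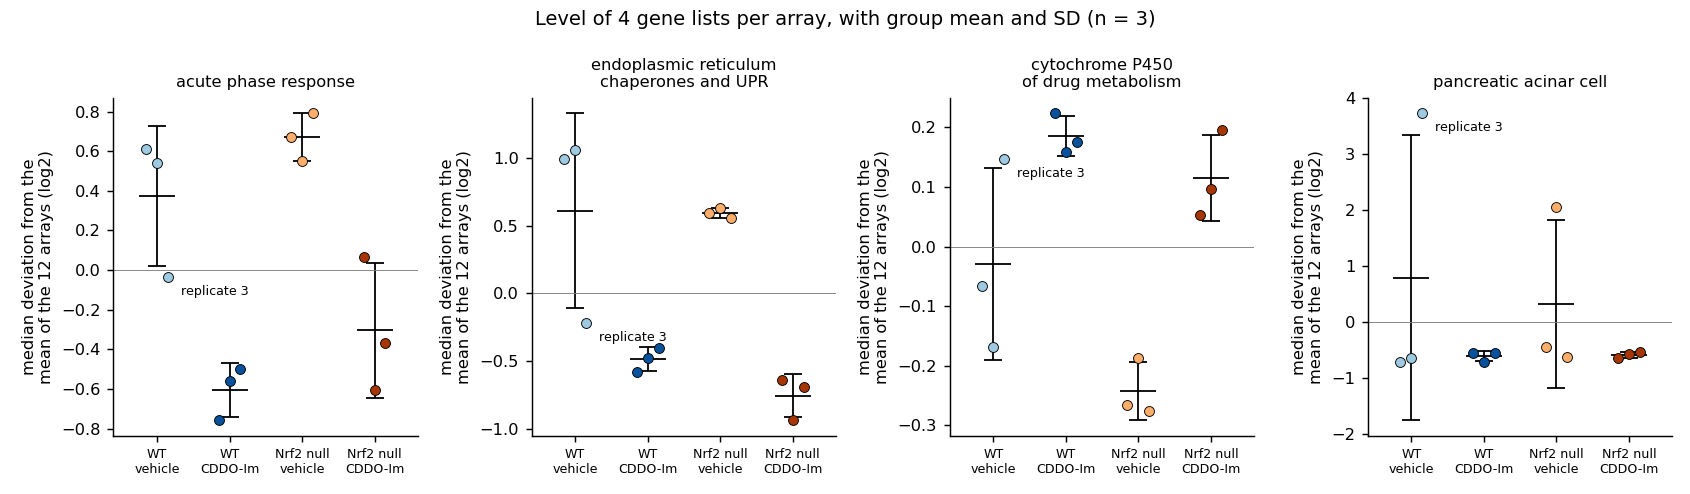
Level of 4 lists on each of the 12 arrays as the median log2 deviation of the members from their mean over all arrays, 1 point per array, with a bar at the group mean and whiskers of 1 SD (n = 3). Wild type vehicle replicate 3 lies at -0.22 in the chaperone list, below the other vehicle arrays, and at 3.74 in the pancreatic acinar list.

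Without the compound, the comparison of Nrf2 null with wild type livers asked what the absence of Nrf2 changes at baseline. Besides Nfe2l2, few genes passed. Cyp2d13 (Entrez Gene 68444), a P450 family member, was 8.63-fold lower in Nrf2 null (-3.11 ± 0.23, SE, n = 3 per group, adjusted p = 0.000145). Wfdc2, a secreted protein of the whey acidic protein family, fell by 2.03 (adjusted p = 0.000978), and Aox1, an aldehyde oxidase, fell by 1.86 (adjusted p = 0.0169), with 1 of its Nrf2 null values (5.77) below the array median. Nfe2l2 lay below it on all 6 Nrf2 null arrays. Ctse, the protease cathepsin E, was higher by 2.40 ± 0.20 (adjusted p = 0.000287), Cxcl1 by 1.94 (adjusted p = 0.000349) and Cst3, a protease inhibitor, by 1.31 (adjusted p = 0.000349). Nqo1 (-0.28, adjusted p = 0.158), Gclc (-0.75, adjusted p = 0.215), Gclm (-0.31), Txnrd1 (-0.33), Hmox1 (-0.09) and Srxn1 (0.01) did not pass. Since Nqo1 read below the array medians on all vehicle arrays, a lower level in Nrf2 null would be hard to see.

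Several lists shifted between the vehicle groups, and none of them held its call with an estimated correlation. Quinone, carbonyl, epoxide and ester detoxification genes were lower in 1 of 20 cases, Aox1, or 8 adjusted over the list alone (camera adjusted p = 1.22e-06, and adjusted p = 0.204 with an estimated correlation). Fatty acid oxidation genes were lower in 2 of 25 cases, or 13 adjusted over the list alone, namely Ppara at -1.13 and Cd36, a fatty acid transporter, at -0.81 (camera adjusted p = 2.91e-11, and adjusted p = 0.237 with an estimated correlation). Nrf2 pathway regulators passed as a set (camera adjusted p = 0.00345, and adjusted p = 0.123 with an estimated correlation), which the disrupted Nfe2l2 itself brought about, and the 9 other members had a camera adjusted p of 0.138, with none called over all genes. Cholesterol synthesis genes had a mean difference of 0.49 with no member called (camera adjusted p = 0.000343, and adjusted p = 0.541 with an estimated correlation). The lists of glucuronidation (-0.31), efflux transporter (-0.32), cytochrome P450 (-0.38), acute phase (0.36) and heat shock genes (-0.38) passed as sets by these mean differences (camera adjusted p = 0.000442, 0.00254, 0.00124, 0.0041 and 0.000402). With an estimated correlation the adjusted p was 0.494, 0.464, 0.446, 0.739 and 0.494. Without wild type vehicle replicate 3 the mean differences shrank to -0.04, -0.17, -0.22, 0.08 and -0.12. The camera adjusted p was then 0.115, 0.179, 0.0906, 0.814 and 0.146, and without Nrf2 null vehicle replicate 3 the acute phase list had 0.0585. The thioredoxin, peroxiredoxin, heme and iron (-0.09), ATF4 (-0.25), p53 (0.19), male-biased (0.30), Kupffer cell (-0.25) and stellate cell lists (-0.30) also passed, and the calls of these 6 ended when single arrays were left out. In that order the camera adjusted p was 0.0148, 0.013, 0.026, 0.00885, 0.0428 and 0.00271, and with an estimated correlation it was 0.204, 0.519, 0.494, 0.541, 0.743 and 0.327. Their adjusted p rose to 0.0966 without Nrf2 null vehicle replicate 1, 0.197 without wild type vehicle replicate 2, 0.387 without wild type vehicle replicate 3, 0.119 without wild type vehicle replicate 1, and 0.946 and 0.0966 without Nrf2 null vehicle replicate 2. Of the lists that did not pass with all arrays, the chaperone list did in 3 of 24 alternatives, with an adjusted p down to 5.5e-08 and a mean of -0.46 without wild type vehicle replicate 3. Acinar markers did in 5, endothelial markers in 4 and glutathione S-transferases, interferon response and proteasome genes in 1 each.

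With vehicle 71 genes passed limma's test at an adjusted p under 0.05, 21 higher and 50 lower in Nrf2 null, and 2410 had an unadjusted p under 0.05. Groups did not overlap for 17.0% of all genes, where chance gives 10%. Leaving out wild type vehicle replicates 1, 2 or 3 changed the count to 26, 41 or 219, Nrf2 null vehicle replicates 1, 2 or 3 to 19, 21 or 110, wild type CDDO-Im replicate 3 to 46 and Nrf2 null CDDO-Im replicate 2 to 38. It was 117 without both arrays that carried acinar transcripts, 1477 with array weights, 40 with array medians aligned, 18 with the compared arrays alone and 16 at an adjusted p under 0.01. The calls of Nfe2l2, Cyp2d13, Wfdc2, Ctse, Cxcl1 and Cst3 held whichever array was left out, and that of Ctse ended with the mean of its probe sets. Aox1 had an adjusted p of 0.106 without Nrf2 null vehicle replicate 1. Ppara and Cd36 had 0.158 and 0.169 without wild type vehicle replicate 1 and lost their calls in 7 and 10 such fits.

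Under CDDO-Im the same comparison asked which genes came to different levels in the genotypes. Several genes that CDDO-Im raised in wild type were lower in Nrf2 null livers. Abcc3 (Entrez Gene 76408), which exports glucuronides, was 20.5-fold lower in Nrf2 null (-4.36 ± 0.35, SE, n = 3 per group, adjusted p = 4.85e-05), and Srxn1 6.96-fold lower (-2.80 ± 0.07, adjusted p = 1.59e-09). With vehicle Abcc3 already read lower in Nrf2 null (7.23, 6.97 and 7.26) than in wild type (8.58, 8.10 and 9.86). The interaction was not called for Abcc3, nor for Gclc, Gclm, Gsta2, Aox1, Fgf21 and Lyve1, given below. With vehicle Aox1 already differed by -1.86. Fgf21 read 6.56, 7.17 and 7.74 in Nrf2 null with vehicle against 8.11, 8.01 and 7.93 in wild type. Nqo1 was lower, at -2.31, as were Gclc (-2.48), Gclm (-1.01), Txnrd1 (-1.81), Gsta2 (-3.10), Ces1g (-3.77) and Aox1 (-3.06). Nqo1 and Ces1g read below the array medians in Nrf2 null, as did Lyve1. Fgf21 was lower, at -2.76 (adjusted p = 0.000535), and so was Lyve1, at -1.92 (adjusted p = 0.00412). Thrsp (Entrez Gene 21835), which promotes fat synthesis, was 9.38-fold higher in Nrf2 null (3.23 ± 0.40, adjusted p = 0.00122), and Ctse was higher by 2.13. Hmox1 did not pass (-0.57, adjusted p = 0.11).

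Lists of Nrf2 targets differed under CDDO-Im, and some held with an estimated correlation. Thioredoxin, peroxiredoxin, heme and iron genes were lower in 6 of 16 cases, or 8 adjusted over the list alone (camera adjusted p = 1e-11, and adjusted p = 0.00913 with an estimated correlation). Quinone, carbonyl, epoxide and ester detoxification genes were lower in 7 of 20 cases, or 11 adjusted over the list alone (camera adjusted p = 9.59e-20, and adjusted p = 0.0373 with an estimated correlation). NADPH suppliers were lower in 3 of 7 cases, with the same count adjusted over the list alone (camera adjusted p = 1.53e-08, and adjusted p = 0.0464 with an estimated correlation). Glutathione synthesis genes were lower in 3 of 10 cases, or 4 adjusted over the list alone (camera adjusted p = 4.39e-06, and adjusted p = 0.0412 with an estimated correlation). Nrf2 pathway regulators include the disrupted Nfe2l2. Without it the other 9 had a mean difference of -0.20 (camera adjusted p = 0.0021, and adjusted p = 0.126 with an estimated correlation), and Mafg (-0.52) alone was called. That alternative, chosen after the data had been seen, also raised the adjusted p of other lists with an estimated correlation, which are adjusted together. NADPH suppliers then had 0.0522, while glutathione synthesis (0.0481), quinone detoxification (0.0457) and thioredoxin genes (0.00913) still passed. Cholesterol synthesis genes were higher in 2 of 20 cases, Sc5d by 0.91 and Ebp by 0.66, or 12 adjusted over the list alone (camera adjusted p = 7.09e-12, and adjusted p = 0.23 with an estimated correlation). Their median was 0.81 in Nrf2 null CDDO-Im replicate 1 against 0.01 and -0.03 in replicates 2 and 3. Heat shock genes were lower in 3 of 18 cases, or 8 adjusted over the list alone, with Hsp90aa1 at -1.18 (camera adjusted p = 4.35e-09, and adjusted p = 0.23 with an estimated correlation). Ribosome biogenesis genes were lower in 3 of 25 cases, or 8 adjusted over the list alone (camera adjusted p = 8.35e-09, and adjusted p = 0.144 with an estimated correlation). By mean differences, the lists of glutathione S-transferase (-0.75), glucuronidation (-0.74), efflux transporter (-0.59) and ATF4 genes (-0.35) passed, as did those of fatty acid synthesis (0.42), fatty acid oxidation (-0.42), acute phase (0.48) and male-biased genes (0.58). In that order the camera adjusted p was 1.68e-05, 5.6e-08, 1.07e-06, 2.75e-05, 0.000917, 7.01e-05, 3.37e-06 and 0.000695, and with an estimated correlation none of the 8 passed (adjusted p = 0.439, 0.237, 0.23, 0.237, 0.446, 0.532, 0.532 and 0.439). The calls of the cytochrome P450 (-0.17), chaperone (-0.24), gluconeogenesis (0.15) and clock lists (0.19) ended when single arrays were left out, with an adjusted p of up to 0.144 without wild type CDDO-Im replicate 2, 0.311 without Nrf2 null CDDO-Im replicate 2, and 0.109 and 0.289 without wild type CDDO-Im replicate 1. With all arrays their camera adjusted p was 0.0392, 0.0186, 0.028 and 0.0151, and with an estimated correlation none passed (adjusted p = 0.652, 0.743, 0.271 and 0.439). Without wild type CDDO-Im replicate 2 Mafg had an adjusted p of 0.164, the highest over the arrays left out, and its call ended in 8 such fits. Kupffer cell, interferon response and proteasome lists, which did not pass, did in 1 of 24 alternatives each.

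Under CDDO-Im 263 genes passed limma's test at an adjusted p under 0.05, 113 higher and 150 lower in Nrf2 null, 92 of them at least 2-fold, and 2064 had an unadjusted p under 0.05. Groups did not overlap for 16.8% of all genes, where chance gives 10%. Leaving out wild type CDDO-Im replicates 2 or 3 changed the count to 151 or 162 and wild type vehicle replicate 3 to 464. It was 411 without both arrays that carried acinar transcripts, 467 with every probe set and 123 at an adjusted p under 0.01. The calls of Abcc3, Srxn1, Nqo1, Gclc, Gclm, Txnrd1, Gsta2, Ces1g, Aox1, Fgf21, Lyve1, Thrsp, Ctse, Sc5d, Ebp and Hsp90aa1 held whichever array was left out, and those of Ctse and Sc5d ended with the mean of their probe sets. Both genotype comparisons called 22 genes in the same direction, 8 higher and 14 lower in Nrf2 null, where 0.54 would be shared if the calls were independent. The compared groups share no array, but both comparisons take their spread from all 12 arrays. Nfe2l2, Cyp2d13, Wfdc2, Aox1, Ctse and Cst3 were among them. Wfdc2 had -1.11 in the CDDO-Im comparison, lost its call there in 4 of 12 fits that left out an array and had an adjusted p of 0.0813 without wild type CDDO-Im replicate 2.

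With all arrays several other lists did not pass as sets with the compound in either genotype. Proteasome genes had 1 of 34 members raised in wild type, Psmd5 by 0.50, and a camera adjusted p of 0.773 there and 0.366 in Nrf2 null. In wild type and Nrf2 null, in that order, the adjusted p was 0.549 and 0.0548 for p53 targets, 0.618 and 0.105 for ATF4 and integrated stress response genes, and 0.366 and 0.594 for cell cycle and DNA replication genes. It was 0.732 and 0.0852 for gluconeogenesis, glycolysis and insulin response genes, of which 4 of 15 rose in Nrf2 null, or 5 adjusted over the list alone. Among these Gckr, which controls glucokinase, rose by 1.23, with an adjusted p of 0.0569 without Nrf2 null vehicle replicate 1 and 0.056 without Nrf2 null CDDO-Im replicate 3. The adjusted p was 0.43 and 0.0852 for male-biased liver genes, with means of 0.19 and 0.48, and 0.971 and 0.763 for female-biased liver genes. Some of these sets passed in alternatives. In Nrf2 null p53 targets did so in 11 of 24, male-biased genes in 5, ATF4 genes in 4, gluconeogenesis genes in 3 and proteasome genes in 2. In wild type male-biased genes passed in 3 and proteasome genes in 1. In Nrf2 null the adjusted p fell to 0.0121 for p53 targets without Nrf2 null vehicle replicate 1, 0.0118 for proteasome genes with cyclic loess, 0.0185 for gluconeogenesis genes with the mean of probe sets and 0.0156 for male-biased genes without wild type vehicle replicate 3. For ATF4 genes it fell to 0.0106 there without both arrays that carried acinar transcripts. In wild type it fell to 0.00606 for male-biased genes without both these arrays and 0.00992 for proteasome genes without wild type CDDO-Im replicate 1. Nrf2 pathway regulators rose in 2 of 10 cases in wild type, Mafg by 0.58 and Maff by 0.52 (camera adjusted p = 0.0219, and adjusted p = 0.204 with an estimated correlation), and without wild type vehicle replicate 3 or wild type CDDO-Im replicate 2 the list's adjusted p was 0.175 or 0.0995. Mafg and Maff lost their calls in 4 and 7 fits that left out 1 array, and Psmd5 in 5. In Nrf2 null the regulators did not pass (camera adjusted p = 0.366).

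Bile acid synthesis and uptake genes passed as a set in wild type (camera adjusted p = 0.0183, and adjusted p = 0.378 with an estimated correlation), and without wild type vehicle replicate 2 or wild type CDDO-Im replicate 2 the adjusted p was 0.0615 or 0.191. Interferon response genes did too (camera adjusted p = 0.00135, and adjusted p = 0.422 with an estimated correlation), with 0.0534 without wild type vehicle replicate 3. Cholesterol synthesis genes passed with a mean difference of -0.25 (camera adjusted p = 0.0479, and adjusted p = 0.743 with an estimated correlation), and the adjusted p was 0.804, 0.14, 0.0551 or 0.0523 without wild type vehicle replicate 3, wild type CDDO-Im replicates 1 or 3, or Nrf2 null vehicle replicate 2. With all arrays fatty acid synthesis genes did not pass in wild type (camera adjusted p = 0.366), cytokines and NF-kB targets had 0.414 there, and in Nrf2 null cholesterol synthesis and ribosome biogenesis genes had 0.344 and 0.652. Fatty acid synthesis in wild type passed in 2 of 24 alternatives (0.03 and a mean of 0.22 without wild type vehicle replicate 3). Cholesterol synthesis in Nrf2 null passed in 2, at 0.015 without Nrf2 null CDDO-Im replicate 1, where its mean was -0.31 against 0.05 with all arrays.

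With all arrays no list of liver cell type markers passed as a set with CDDO-Im. In wild type and Nrf2 null, in that order, the camera adjusted p was 0.542 and 0.366 for hepatocytes, 0.201 and 0.0883 for Kupffer cells and macrophages, 0.976 and 0.457 for neutrophils, and 0.794 and 0.522 for lymphocytes. It was 0.406 and 0.325 for endothelial cells, 0.07 and 0.344 for stellate cells and fibroblasts, 0.89 and 0.161 for cholangiocytes, 0.987 and 0.962 for erythroid cells and 0.28 and 0.344 for adipocytes. Some of them passed in alternatives, namely Kupffer cells in 5 of 24 in Nrf2 null (down to 0.00479, mean 0.42, without Nrf2 null vehicle replicate 3) and in 2 in wild type (0.000261, mean 0.40, without wild type vehicle replicate 1). Without Nrf2 null vehicle replicate 2 the mean of the Kupffer cell list in Nrf2 null was 0.01. Stellate cells passed in 3 in wild type (0.0101, mean -0.29, without wild type vehicle replicate 1), and endothelial cells in 1 there (0.0397, mean -0.08, without both arrays that carried acinar transcripts) and in 2 in Nrf2 null (0.021, mean 0.22, with array weights). Within the adipocyte list Fabp4 fell in both genotypes and no other member passed, and in wild type the list's median was 0.02 beside a mean of -0.61. In wild type the median and the mean also had opposite signs for neutrophil (0.10 and -0.07), endothelial (-0.17 and 0.01), cholangiocyte (-0.0053 and 0.0127) and erythroid markers (-0.0098 and 0.0304). In Nrf2 null they did for neutrophil (0.02 and -0.20) and erythroid markers (-0.001 and 0.0385).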

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

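The tests of what lies behind the 3 patterns weighed here were chosen after the results had been seen, and the counts over other splits of the arrays were planned.

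The effect of CDDO-Im differed between wild type and Nrf2 null livers for 25 genes, by the interaction test, and these genes stand out for that reason. Their differences (log2, wild type effect minus Nrf2 null effect) were 3.95 for 9130409I23Rik, whose name is that of a clone and which is given after its values were seen, 3.03 for Ces1g, 2.81 for Srxn1, 2.75 for Gstm4, 2.71 for Gstm3, 2.50 for Pgd and 2.43 for Pir. They were 2.17 for Ugdh, 2.03 for Cbr1, 2.03 for Nqo1, 1.95 for Cbr3, 1.88 for Cxcl1, 1.80 for Gsr, 1.60 for Blvrb, 1.52 for Ugt2b35, 1.52 for Osgin1 and 1.48 for Txnrd1. The smaller ones were 1.30 for Slc48a1, 1.12 for Tkt, 1.12 for Cds2, 1.12 for Arpp19, 0.84 for Cdc34, 0.67 for Dcaf12, -0.62 for Lgr4 and -1.12 for Sc5d, of which Cds2, Arpp19, Cdc34 and Dcaf12 are named after their values were seen. 9130409I23Rik, Ces1g, Nqo1 and Cbr3 read below the array medians in all groups but wild type with CDDO-Im, so their sizes are uncertain. Leaving out 1 array ended the call of Ugdh, Tkt, Sc5d and Lgr4 in 10 of 12 fits each, of Cdc34 and Dcaf12 in 11, of Slc48a1 and Arpp19 in 8, of Cds2 in 6 and of Osgin1 in 5, and of none of the other 15, with an adjusted p of up to 0.173, reached by Dcaf12 without wild type vehicle replicate 1. As sets, the lists with a higher mean difference were NADPH suppliers (0.69), quinone detoxification (0.63), glutathione S-transferases (0.61), glutathione synthesis (0.56), thioredoxin, heme and iron (0.55), glucuronidation (0.43), efflux transporters (0.27), ribosome biogenesis (0.24) and heat shock (0.16). Those with a lower one were fatty acid synthesis (-0.44), stellate cell markers (-0.35), cholesterol synthesis (-0.30), clock genes (-0.29), gluconeogenesis (-0.24) and fatty acid oxidation (-0.16). Of these 15 sets, those of glutathione synthesis and of thioredoxin, heme and iron also passed with an estimated correlation, the former at 0.0464 and no longer (0.0522) once Nfe2l2 was left out of the list of regulators adjusted with it. Leaving out 1 array ended the calls of 7 of them, with an adjusted p of up to 0.272 for efflux transporters without wild type vehicle replicate 2, 0.336 for heat shock and 0.0635 for glucuronidation without wild type vehicle replicate 1, 0.147 for gluconeogenesis without wild type vehicle replicate 3, 0.72 for fatty acid oxidation without wild type CDDO-Im replicate 3, 0.0772 for stellate cell markers without Nrf2 null vehicle replicate 2 and 0.946 for cholesterol synthesis without Nrf2 null CDDO-Im replicate 1.

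Among 10092 probe sets that name several genes or none, which no comparison above uses, 51 passed for CDDO-Im in wild type, 189 for CDDO-Im in Nrf2 null, 7 and 36 between genotypes with vehicle and with CDDO-Im, and 7 for the interaction. Vehicle or wild type arrays of the same comparison were the control.

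Other splits of the arrays were counted for each comparison. For CDDO-Im in wild type 1 of the 10 splits of the 6 arrays, the real one, gave as many genes as the 332 called, and the highest other gave 72. For CDDO-Im in Nrf2 null it was again 1 of 10, with 1074 against 1, for genotype with vehicle 1 of 10, with 71 against 4, and for genotype with CDDO-Im 1 of 10, with 263 against 0. With 10 splits the share cannot fall under 0.05. For the interaction, 10 of 100 splits drawn from 200 gave at least the 25 genes called, and the highest other split gave 643. All 10 of them, the real one included, divided the CDDO-Im arrays by genotype, and the splits that did not divide them so gave at most 15. In 5 of the 10 the CDDO-Im labels were exchanged in full, among them the split with 643, where the contrast becomes the genotype effects added up. In the other 5, the real one included, these labels were the real ones and the rest exchanged vehicle arrays (53, 47, 43 and 33 genes). By the rule set beforehand, a share of 0.05 or more goes with chance, and 10 of 100 reached it. However, all these splits keep the CDDO-Im arrays of each genotype together and so carry a structure of the samples. By this reading, which was not part of the rule, the count neither excludes chance nor speaks for it.

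Wild type vehicle replicate 3 lay closer to the CDDO-Im arrays than the other vehicle arrays did, yet 6 Nrf2 target genes reached a median share of -0.0264 of the wild type shift, which argues against a treated wild type mouse under a wrong label. A treated Nrf2 null mouse is argued against by Nfe2l2, which was higher by 0.13 than in the other wild type vehicle arrays. Pancreatic tissue in the sample, for which 10 acinar markers were 4.39 higher (median, 5.43 for Cela2a and 5.14 for Cpa1), is argued against as the whole cause by the chaperone genes. Acinar cells are rich in these, yet their median fell by 1.18 relative to that of hepatocyte markers, with 18 of 19 below every hepatocyte marker, while the acute phase list, the first choice for this test, fell by 0.60 and left it undecided, after which the chaperone list was taken. In Nrf2 null vehicle replicate 2 acinar markers were 2.65 higher than in the other vehicle arrays of that genotype. Its chaperone, acute phase and cytochrome P450 medians differed by 0.08, -0.09 and 0.03. Kupffer cell markers were lower in both arrays with acinar transcripts (-0.63 in wild type, -0.81 in Nrf2 null). That is 1 array with fewer acinar transcripts, which cannot settle the question. What put the wild type sample with the treated ones stays open, and acinar RNA as a part of it too.

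In Nrf2 null livers the acute phase and chaperone lists were lower and several lists of metabolic genes higher under CDDO-Im by camera. With an estimated correlation no list passed there (0.242 and 0.23 for the first 2). That correlation was estimated from all 12 arrays, wild type vehicle replicate 3 included, and not without it. The SD of the chaperone list level was 0.72 in wild type vehicle against 0.04 to 0.16 in the other groups. Remaining Nrf2 activity was weighed by 6 target genes. Among them Srxn1, Nqo1 and Txnrd1 had effects of 2.19, 2.07 and 1.21 in wild type but -0.62 (called lower), 0.04 and -0.27 in Nrf2 null. They were picked out by these values, which argue against it for these genes alone. The median effect of the same 6 target genes in Nrf2 null was 0.0688. It lies between Nqo1, below the array medians there, and Hmox1, which did not pass in wild type either. Gclc was called higher (1.23), and Gsta2 and Aox1 rose in both genotypes, so for those genes it stays open. It also stays open for the acute phase, chaperone and metabolic lists, which the 6 genes do not measure. Fewer macrophages are argued against by their markers (median 0.33 over all 12, and over the 9 bright ones a lower quartile of 0.11, or -0.17 with a median of 0.01 without Nrf2 null vehicle replicate 2, where a loss would need -0.5), but fewer neutrophils (median 0.0166, mean -0.20, S100a8, below the array medians with CDDO-Im, -1.27 and S100a9 -0.95 called lower), lymphocytes (median -0.0404) or adipocytes (median -0.0244, mean -0.86, Fabp4 -5.74 called lower) cannot be told apart from this pattern, since 1, 2 and 2 of their markers lay above the 75th percentile of all probe sets, a limit set after list medians, and then a limit at the median of all probe sets, had argued against all 4, and the arrays left out were added later still. A state that vehicle mice can also have was weighed by the deviation of wild type vehicle replicate 3 from the other wild type vehicle arrays. Over the 1074 genes called there it correlated with the effect at r = 0.912, and 955 had the same sign. Genes are not independent. The effect comes from other arrays, but the choice of genes rests on a spread estimated from all 12. Over all genes r was 0.557. This array was picked because it lay with the CDDO-Im arrays, so a high correlation follows from that choice and cannot decide the question. Such a state stays open, as do an effect of the compound without Nrf2 and whatever the mark on the vehicle titles stands for.

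Of 21 genes with a chromosome that differed between genotypes both with and without CDDO-Im, Nfe2l2 left out, 6 lie on the chromosome that carries Nfe2l2 (28.6% against 7.75% of all genes, odds ratio 4.77, Fisher's exact p = 0.00423, two-sided). They are Fam171b, Ptpmt1, Cd59a, Cst3, BC029722 and Wfdc2, at 33, 73, 151, 513, 621 and 726 tested genes from Nfe2l2 among 1399, and those outside the naming rule were chosen after their values were seen. DNA from the strain in which the locus was disrupted may therefore account for some of them, although the last 3 are far from the locus and no such excess was seen among all genes called with vehicle (7 of 70) or with CDDO-Im (23 of 262). Sequence differences under single probe sets cannot be told apart from changed expression, since another probe set exists for 2 of the 6 genes and moved the same way for both (-0.75 and -0.90 for Cd59a, -0.58 and -0.72 for Fam171b, with vehicle and with CDDO-Im), by at least 0.5 times as much as the first for 1 of them, too few after a minimum of 5 genes was set once this value was known, without which the test would have argued against it. The other probe set of Fam171b had a mean of 4.87, below the array medians, and its first lay below them on all Nrf2 null arrays. How the sizes of its 2 probe sets compare is therefore uncertain. Lack of Nrf2 itself cannot be told apart either. The 13 genes lower in both had a median wild type effect of CDDO-Im of 0.0464, with 3 higher and 1 lower.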

How the results depend on the processing

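Leaving out the 2 arrays with acinar transcripts together, and Nfe2l2 from the list of regulators, were tested after the data had been seen, and the other alternatives were planned. Over the fits that left out 1 array, the genes called ran from 104 to 1385 for CDDO-Im in wild type (332 with all arrays), 97 to 1615 in Nrf2 null (1074), 19 to 219 for genotype with vehicle (71), 151 to 464 for genotype with CDDO-Im (263) and 15 to 46 for the interaction (25). Wild type calls that differed by genotype ran from 14 to 44 (23), calls shared by the genotypes from 28 to 772 (148) and list tests passed from 77 to 87 (81). Every upper end but that of the lists came without wild type vehicle replicate 3. In the order wild type, Nrf2 null, vehicle, CDDO-Im, interaction, differing and shared, array weights gave 2023, 1897, 1477, no change beyond 1.5 times, 89, 72 and 758. Without both acinar arrays wild type gave 1293, vehicle 117, CDDO-Im 411, the interaction 39, differing 36 and shared 637. An adjusted p under 0.01, stricter by construction, gave 109, 97, 16, 123, 15, 14 and 11. Every probe set gave 549 in wild type, 467 with CDDO-Im, 57 for the interaction and 52 differing. The compared arrays alone, which are fewer, gave 110 in wild type, 18 with vehicle and 40 shared, and do not apply to the interaction. Aligned medians gave 40 with vehicle and 86 shared, and a 1.5-fold minimum 624 in Nrf2 null. With the replicate block the 7 counts were 323, 1000, 80, 231, 20, 19 and 160. Of 81 list tests 9 passed with an estimated correlation and 36 by fry. Without Nfe2l2, whose level the genotype fixes, in the regulator list it was 80, 6 and 35. Directions reversed for the acinar list in wild type, from a mean of -1.36 to 0.0884 without wild type vehicle replicate 3 (-2.10 to 0.0884 over the arrays left out) and to 0.0884 without both acinar arrays, where the array left out held its transcripts. They did so for cholesterol synthesis in the interaction without Nrf2 null CDDO-Im replicate 1 (0.0596, with -0.50 to 0.0596 over the arrays left out), Cux2 in Nrf2 null with the mean of its probe sets (0.16) and Nfe2l2 by its dimmer probe set (0.14 with vehicle, 0.24 with CDDO-Im). In the interaction the mean of fatty acid oxidation genes also changed sign without wild type CDDO-Im replicate 3 (0.004) and that of heat shock genes without wild type vehicle replicate 1 (-0.0061), where camera's direction did not. The chaperone list, not called for the interaction, had a positive median with all arrays and a negative mean without wild type vehicle replicate 3. For the other changes the cause was not tested. Of 327 calls of named genes 147 held whichever array was left out and 132 in every alternative, and of the 81 list tests passed 54 and 8. No scaling moved the median of all genes by over 0.1. The arrays give no depth, and signal over background was not used here.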
